A study of Bos taurus with 18 samples.

How the data were processed

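Small RNA was sequenced from papillae of the rumen, the forestomach in which feed is fermented, of 9 Holstein cows that were not in milk. Per the design text, the cows ate forage only (FD) and were then moved to a high-grain diet with 65% concentrate (HG), and 5 of them were controls (CON) while 4 received a supplement labelled PHY. The labels give 18 libraries in 4 groups, with 5 libraries each in FD_CON and HG_CON and 4 each in FD_PHY and HG_PHY. What PHY stands for is not given in the sources used here, nor is whether the supplement was already fed when the FD_PHY samples were taken. All forage samples preceded the grain samples, so diet and time could not be separated. Per the labels' protocols, RNA was extracted with the NucleoSpin miRNA kit and libraries were made with the NETflex Small RNA-Seq kit. The submitters' processing notes name bcl2fastq 2.20 and DESeq2, the latter without a version or a role. The aligner, the counting program and the genome build are not given in the sources used here.

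Per the file headers, the deposited file of each library gives for every mature miRNA name a raw read count, an expected count in which the authors divided reads over the names and loci they map to, and RPM, reads scaled by the total, of the reads assigned to miRNAs and of all reads. A read that fits several names was counted for each by the authors, so the RPM of the assigned reads adds up to more than its base in a library. The RPM columns served here only to find the read totals. A column that marks names as duplicates has no stated meaning and was not used. A deposited table of the whole series holds a normalized signal, made by the authors from the adjusted counts, for 673 names, 500 of them bovine (bta) and 173 human (hsa). With 1 size factor per library, the median ratio of the rounded adjusted counts to the values over well-covered names, 100% of the values became whole reads within 0.01 reads, and every recovered value equalled the rounded adjusted count.

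The library files list 966 names, 759 bovine and 207 human. Names at overlapping positions (at least 15 nt), or a bovine and a human name for the same miRNA with totals within 5%, were taken as 1 miRNA, which left 824 miRNAs, 141 of them with several names. This merging was set once the layout of the names was seen. Each miRNA was represented by the name with the highest total over all libraries, as fixed beforehand, because a read can be counted under several names. For miR-21-5p, for example, the adjusted count of the name used was 0.5 of its raw count, while for miR-143 the ratio was 1.0. Members of a family that share reads, such as those of the let-7, miR-29 and miR-30 families, are therefore uncertain. Names without a prefix in the text are bovine entries, and human entries are marked (hsa). Only chromosomes are given for positions. Of 612 positions tested against the RefSeq table of bovine genes, 0 lay within 200 nt of the gene of the same name, so no coordinates are printed.

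Reads counted once per miRNA came to between 5.74 and 15.2 M (mega-reads) per library, out of 19.52 to 42.65 M reads in all. Between 27.0% and 48.6% of the reads were assigned to miRNAs, and 515 to 591 miRNAs were seen per library. Replicate libraries differed by far more than counting noise. The chi-square per degree of freedom of a pair within a group lay between 125.8 and 2930, so no library was treated as a copy of another. A total of 468 miRNAs passed edgeR's filterByExpr. They were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the raw counts, scaled by TMM, in a model with a mean for each of the 4 groups and all 18 libraries. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold, two-sided. The 6 comparisons were the diet effect averaged over both arms (the main comparison), the diet effect in CON and in PHY, PHY against CON on forage and on grain, and the diet by supplement interaction. No term for the cow was used, so p-values treat 18 libraries from 9 cows as independent. Levels are CPM, raw counts scaled by TMM to a common library size, given as mean ± SD over libraries, and effects are log2 fold changes ± SE. Where libraries are counted as higher or lower, they are set against the mean of the other group, which a single high library can raise.

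The comparisons, the tests, the miRNA lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. The rule took, among miRNAs past the threshold with a mean of at least 10 CPM, the 12 largest rises and 12 largest falls for the main comparison and 6 and 6 for each other comparison. Where fewer than 5 passed, it added the 5 with the lowest p, said not to pass. It also took up to 4 measured members of each list with the lowest p in the main comparison, and the 10 most abundant miRNAs as a description. The 18 lists were the epithelial miR-200 family, stratified epithelium and keratinocyte, muscle, leukocyte, erythroid, endothelial, mesenchymal and fibroblast, columnar gut epithelium, neural, the miR-17-92 and paralogous clusters, the let-7 family with miR-98, the miR-29 family, the miR-30 family, inflammation responsive, lipid and energy metabolism, the miR-183 cluster, hypoxia and p53 responsive, and the DLK1-DIO3 imprinted cluster. The muscle, leukocyte, erythroid, endothelial, mesenchymal, columnar and neural lists stand for other cell types that a biopsy of papillae could hold. Some lists share measured members, for example 4 between leukocyte and inflammation responsive, 2 between leukocyte and the miR-29 family, and 4 between mesenchymal and DLK1-DIO3.

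Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between members, adjusted over the lists of a comparison. They were tested again with a correlation estimated from the data, with fry, which asks whether the members move 1 way on balance without comparing them with other miRNAs, and by an exact permutation of the libraries' mean log2 CPM over the list, within arms for the averaged diet effect. No list passed with an estimated correlation, with fry or by the adjusted permutation p in any comparison where these were run. Within an arm or a diet the permutation had few arrangements, 252 in CON, 70 in PHY and 126 on forage. After adjustment over 18 lists a single list could not pass it there, whatever its values. Like the edgeR model, the permutation did not keep the libraries of a cow together. Permutation of list means was not run for the interaction.

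The alternatives were DESeq2's size factors in edgeR, upper-quartile scaling, leaving out the 5 most abundant miRNAs, no filter, a filter of 10 CPM in 4 libraries, summed names, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, only the groups compared, a replicate block in edgeR and in limma-voom, limma-trend on log2(value + 1) of the authors' table, a threshold of 0.1, leaving out each library in turn and, for the lists, the largest member left out and a replicate block. Adjusted counts, the recovered reads, thinning of all libraries to the lowest depth, the list permutation, the lists under the other settings and without each library, and the largest member left out of 1 list at a time were added after the data were seen. On the recovered reads, 448 miRNAs were tested and edgeR called 1 in the averaged diet effect, miR-320a. For the other 5 comparisons it called 0 at the threshold, with between 12 and 46 at an unadjusted p under 0.05.

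The steps were tested on simulated data drawn from the means, dispersions and library sizes of the real libraries, with all miRNAs varying independently, with 200 of the 468 miRNAs changed with diet. For the averaged diet effect, 58.2% of miRNAs changed 1.5-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold were recovered. In CON the shares were 43.3%, 64.2% and 92.4%, and in PHY 28.4%, 59.7% and 89.4%. With fewer miRNAs changed the Benjamini-Hochberg adjustment is stricter, so these shares can overstate the recovery in the real data, where edgeR called 1 miRNA. With nothing changed, 0 miRNAs were called in each of the 6 comparisons by edgeR, with between 12 and 22 at an unadjusted p under 0.05. A leukocyte list shifted by -0.5 was called by camera (adjusted p = 2.23e-13), and 1 other list was called as well. The inflammation and miR-29 lists share 4 and 2 members with the leukocyte list and were partly shifted, so the other call need not be false. Data handling and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.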

Results

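Small RNA libraries of rumen papillae from 9 cows were compared between forage feeding and high-grain feeding, and between control cows and cows given the supplement labelled PHY. Reads counted (in M, mega-reads) came to 11.9 M ± 2.04 (SD, n = 5) in FD_CON, 8.34 M ± 2.17 (SD, n = 4) in FD_PHY, 8.53 M ± 1.63 (SD, n = 5) in HG_CON and 9.26 M ± 3.04 (SD, n = 4) in HG_PHY. The most abundant miRNA was miR-21-5p, with 22.7% ± 2.85 of the reads (SD, n = 18), followed by miR-143 with 13.2% ± 3.17. miR-24-3p (6.21%), miR-26a (4.72%), miR-27b (4.62%), let-7a-5p (4.04%), let-7f (3.34%), miR-205 (2.86%), let-7g (2.26%) and miR-30a-5p (2.21%) completed the 10 most abundant. miR-205, typical of stratified epithelia, averaged 28643 CPM, and miR-143, typical of smooth muscle and other mesenchymal cells, 133130 CPM.

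The main comparison asked which miRNAs differed between forage and grain feeding in both arms together. miR-320a (chromosomes 20 and 8) rose from 2531 ± 279 CPM on forage to 3377 ± 421 CPM on grain (SD, n = 9 each), a log2 change of 0.43 ± 0.09 (SE). It was above the forage mean in 9 of 9 grain libraries. The abundant miR-143 stood at 157406 ± 49780 CPM on forage and 108853 ± 10786 CPM on grain (log2 change -0.51 ± 0.12), and miR-146a, a regulator of inflammatory signalling, at 2035 ± 391 and 1451 ± 395 CPM (log2 change -0.53 ± 0.13). miR-143 was below the forage mean in 9 of 9 grain libraries and miR-146a in 8 of 9. Neither passed the main edgeR test on the 468 miRNAs that passed the filter.

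Of the 468 miRNAs tested with edgeR, 1 passed at an adjusted p under 0.05, miR-320a (adjusted p = 0.0486), and 49 had an unadjusted p under 0.05, 19 higher and 30 lower on grain. The next lowest adjusted p-values were those of miR-143 and miR-146a (both 0.0940). miR-143 passed without FD_CON 2 (adjusted p = 0.0107), HG_CON 2 (0.0479) or HG_CON 3 (0.0421), and miR-146a without FD_PHY 4 (0.0409) or HG_CON 3 (0.0251). With all libraries, both passed in edgeR with no filter (0.0381 and 0.0413), in DESeq2 (0.00553 and 0.0120) and in limma-voom with quality weights (0.0159 each). Fits with the replicate number as a block, given with the alternatives, also called both. In all, miR-143 passed in 9 of 32 alternatives and miR-146a in 8 of 33, the threshold of 0.1 included. hsa-miR-93-5p had a log2 change of 0.28 ± 0.08 and was higher in 8 of 9 grain libraries, miR-671 0.78 ± 0.22 and higher in 8 of 9, and miR-30c -0.38 ± 0.11 and lower in 8 of 9, each with an adjusted p of 0.154. miR-30c passed without HG_CON 2 (adjusted p = 0.0479), and with all libraries in DESeq2 (0.0344) and in edgeR with the replicate block. hsa-miR-93-5p passed in DESeq2 (0.0163). The call of miR-320a ended in 14 of the 18 fits that left out 1 library, with an adjusted p of up to 0.176, and under 5 other settings, while its log2 change stayed positive throughout. It passed without FD_PHY 4, HG_CON 2, HG_CON 3 or HG_PHY 3.

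**Figure D1:**
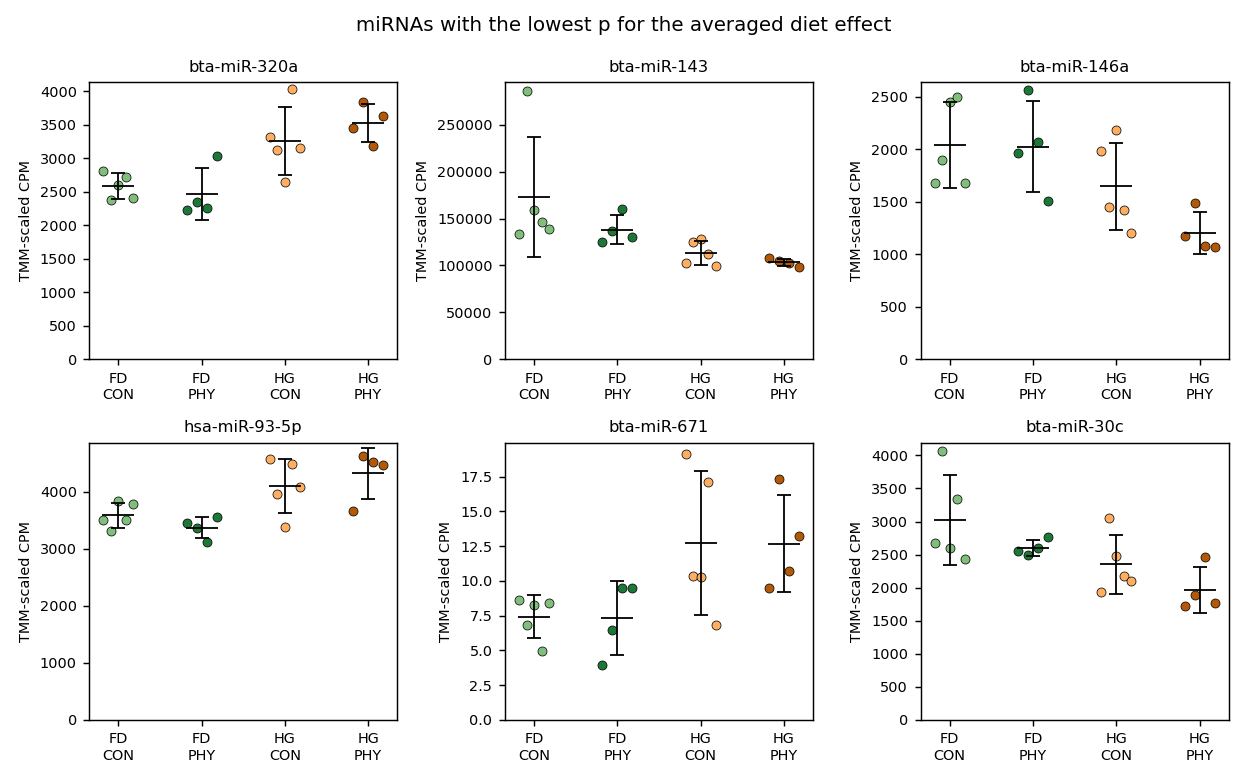
TMM-scaled CPM (counts scaled to a common library size, y axis, linear, from 0) of miR-320a, miR-143, miR-146a, hsa-miR-93-5p, miR-671 and miR-30c in the 4 groups of libraries (x axis), with 1 point per library and the mean and SD of each group as a line and bars. miR-320a averaged 2531 CPM on forage and 3377 CPM on grain, and the highest miR-143 value, in FD_CON 2, was 286183 CPM.

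Among the lists for other cell types, muscle miRNAs were lower on grain in 6 of 6 measured members, with a median log2 change of -0.32 (-0.18 without FD_CON 2). miR-143 led them, followed by miR-145 (-0.46 ± 0.15), hsa-miR-145-3p (-0.35 ± 0.15) and miR-133a (-0.29 ± 0.18), the last 2 at -0.22 and -0.14 without FD_CON 2. Only miR-143, miR-145 and hsa-miR-145-3p had an unadjusted p under 0.05 in edgeR, and the smallest change was -0.08. The estimated correlation between the members was 0.668, so the 6 do not count as independent. Leukocyte miRNAs were lower in 8 of 10 members (median -0.23), among them miR-146a, miR-342 (-0.28 ± 0.10) and miR-142-3p (-0.27 ± 0.13), whereas the myeloid miR-223 had a change of 0.48 ± 0.20. Mesenchymal and fibroblast miRNAs were lower in 9 of 11 members (median -0.15, and -0.08 without HG_PHY 3), with miR-199b at -0.29 ± 0.12, miR-199a-5p at -0.25 ± 0.10, miR-10b at -0.27 ± 0.13 (-0.18 without FD_PHY 4) and miR-152 at -0.17 ± 0.10. The miR-29 family, known for targeting collagen transcripts, was lower in 8 of 9 members (median -0.25), with miR-29a at -0.26 ± 0.09, miR-29b at -0.21 ± 0.10, hsa-miR-29a-5p at -0.43 ± 0.21 and miR-29d-3p at -0.31 ± 0.18.

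These 4 lists passed camera's test with the preset correlation. The muscle list had an adjusted p of 0.0148 (adjusted p = 0.532 with an estimated correlation), the leukocyte list 0.0256 (adjusted p = 0.532 with an estimated correlation), the mesenchymal list 0.0256 (adjusted p = 0.748 with an estimated correlation) and the miR-29 family 0.0180 (adjusted p = 0.532 with an estimated correlation). The mean log2 CPM was below the forage mean in 8 of 9 grain libraries for muscle, 8 of 9 for leukocyte, 6 of 9 for mesenchymal and 9 of 9 for miR-29. It was below every forage library in 7 of 9 for muscle, 4 of 9 for leukocyte, 5 of 9 for mesenchymal and 3 of 9 for miR-29. The exact permutation p of that mean, two-sided and before adjustment, was 0.0121 for muscle, 0.0310 for leukocyte, 0.201 for mesenchymal and 0.00907 for miR-29, and the smallest adjusted value was 0.109. Adjusted over the list alone, edgeR called 2 muscle members (miR-143 and miR-145), 2 leukocyte members (miR-146a and miR-342), 0 mesenchymal members and 0 miR-29 members, against 0 of each over all miRNAs tested. At an unadjusted p under 0.05 there were 3 mesenchymal and 2 miR-29 members, all lower, and DESeq2 called miR-143, miR-145 and miR-146a over all miRNAs. Leaving the largest member out of all 4 lists at once ended all 4 calls. Left out of 1 list at a time, it kept muscle (adjusted p = 0.0473) and miR-29 (0.0277) past the threshold and not leukocyte (0.124) or mesenchymal (0.0772). The leukocyte call also ended without FD_CON 1, FD_CON 3, FD_PHY 2, HG_CON 2, HG_CON 4, HG_PHY 3 or HG_PHY 4 (adjusted p up to 0.0968), and the mesenchymal call without FD_CON 1, FD_PHY 2, FD_PHY 4, HG_CON 1, HG_CON 2, HG_CON 4, HG_PHY 1 or HG_PHY 3 (up to 0.155). With no filter the muscle list had a median of -0.20 and an adjusted p of 0.0554, and with the filter of 10 CPM in 4 libraries the leukocyte list had 0.0509.

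The remaining lists did not pass. Of the epithelial lists, the miR-200 family had 4 of 5 members above 0 (median 0.06, adjusted p = 0.452 by camera), with miR-141 at 0.39 ± 0.16, miR-200a at 0.08 ± 0.11, miR-200b at 0.06 ± 0.11 and miR-200c at -0.04 ± 0.12. The stratified epithelium list had 5 of 7 above 0 (median 0.03, adjusted p = 0.452), with miR-184 at 1.09 ± 0.36, miR-34c at 0.19 ± 0.27, miR-149-5p at 0.13 ± 0.18 and miR-24-3p at 0.03 ± 0.10. miR-184 was the only member called when adjusted over the list alone, at a mean of 4.17 CPM. The signs of miR-200b, miR-200c and miR-24-3p depended on the libraries or the tool.

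Erythroid miRNAs had 3 of 3 members above 0 (median 0.20, adjusted p = 0.452), with miR-486 at 0.36 ± 0.21, miR-451 at 0.20 ± 0.23 and miR-144 at 0.14 ± 0.25, the last of unsteady sign. With 1 library left out, miR-486 came down to 0.18 and miR-451 to 0.03 at the lowest. The endothelial list had 3 of 6 above 0 (median 0.00, adjusted p = 0.674), with miR-126-5p at -0.28 ± 0.11, miR-126-3p at -0.18 ± 0.08, miR-218 at -0.22 ± 0.12 and miR-503-5p at 0.47 ± 0.30. Camera's direction for this list was down although its median was above 0. The columnar gut list had 3 of 6 above 0 (median 0.02, adjusted p = 0.884), with miR-122 at 0.26 ± 0.22, hsa-miR-194-5p at -0.09 ± 0.08, miR-192 at -0.06 ± 0.08 and miR-375, of unsteady sign, at 0.17 ± 0.21; here too camera's direction was down. The neural list had 4 of 8 above 0 (median 0.05, adjusted p = 0.509), with miR-129-5p at 0.53 ± 0.28, miR-7 at 0.14 ± 0.12, hsa-miR-124-3p at 0.16 ± 0.19 and miR-9-3p at -0.13 ± 0.17.

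Of the miR-17-92 and paralogous clusters, 9 of 18 members were above 0 (adjusted p = 0.632 by camera). hsa-miR-93-5p and miR-25 (0.30 ± 0.09), which lie together on chromosome 25, were the 2 members called when adjusted over the list alone, and miR-19b stood at -0.18 ± 0.09 and miR-92a at 0.27 ± 0.14. The let-7 family had 7 of 17 members above 0 (median -0.01, adjusted p = 0.751), with hsa-let-7d-3p at -0.29 ± 0.12, miR-98 at 0.19 ± 0.09, hsa-let-7f-1-3p at -0.24 ± 0.15 and let-7c at -0.26 ± 0.16. In the miR-30 family, 4 of 8 were above 0 (adjusted p = 0.452). miR-30c and miR-30b-5p (-0.41 ± 0.13) were the 2 called when adjusted over the list alone, beside miR-30e-5p at 0.11 ± 0.07 and miR-30d at -0.10 ± 0.08. The inflammation list had 12 of 14 below 0 (median -0.12, adjusted p = 0.0807, but 0.0272 without FD_CON 2, 0.0337 without FD_PHY 3 and 0.0304 without HG_CON 1), and 3 members were called when adjusted over the list alone, miR-146a, miR-125b (-0.43 ± 0.13) and miR-181a (-0.38 ± 0.12).

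In the lipid and energy list 9 of 14 were above 0 (adjusted p = 0.674), and miR-143 was the only member called when adjusted over the list alone, with miR-27a-3p at 0.17 ± 0.09, miR-33b at 0.78 ± 0.50 and miR-378 at 0.12 ± 0.10. The miR-183 cluster had 2 of 3 above 0 (adjusted p = 0.452), with miR-183 at 0.27 ± 0.10, miR-182 at 0.14 ± 0.10 and miR-96 at -0.10 ± 0.12. The hypoxia and p53 list had 4 of 7 above 0 (adjusted p = 0.674), led by the hypoxia-induced miR-210 at 0.41 ± 0.14. The DLK1-DIO3 cluster had 27 of 39 below 0 (median -0.06, adjusted p = 0.509), with the scarce miR-411c-3p at 1.34 ± 0.55, miR-411b at -0.99 ± 0.56, miR-432 at 0.44 ± 0.26 and miR-369-5p at -0.63 ± 0.42 (-0.25 without FD_CON 2).

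In control cows alone, miR-25 stood at 5743 ± 595 CPM on forage and 7744 ± 931 CPM on grain (SD, n = 5 each; log2 change 0.43 ± 0.12), higher in 5 of 5 libraries. Lower in 5 of 5 grain libraries were miR-143 (172736 ± 64143 and 113361 ± 12838 CPM; -0.61 ± 0.17), miR-30b-5p (2520 ± 941 and 1717 ± 238 CPM; -0.55 ± 0.17), miR-2484 (35.4 ± 22.1 and 19.99 ± 3.09 CPM; -0.83 ± 0.28) and miR-199b (689 ± 93.0 and 502 ± 94.4 CPM; -0.46 ± 0.16). FD_CON 2 was the highest forage library for the first 3 of these, and without it their log2 changes were -0.39 for miR-143, -0.34 for miR-30b-5p and -0.40 for miR-2484. Muscle miRNAs were lower in 6 of 6 members (median -0.34), mesenchymal miRNAs in 7 of 11 (-0.21), the let-7 family in 13 of 17 (-0.20) and the miR-29 family in 9 of 9 (-0.25). The muscle median was -0.17 without FD_CON 2 and the miR-29 median -0.39 without HG_CON 4. The mesenchymal median was -0.12 without FD_CON 1, -0.11 without HG_CON 1 and -0.32 without HG_CON 5.

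edgeR called 0 of 468 miRNAs in control cows, with 47 at an unadjusted p under 0.05, and DESeq2, limma-voom and limma-trend on the authors' table also called 0. The adjusted p was 0.334 for miR-25 and miR-143 and 0.402 for miR-30b-5p, miR-2484 and miR-199b. Camera called the 4 lists, muscle at 0.0373 (adjusted p = 0.666 with an estimated correlation), mesenchymal at 0.0414 (adjusted p = 0.666 with an estimated correlation), let-7 at 0.0379 (adjusted p = 0.666 with an estimated correlation) and miR-29 at 0.00860 (adjusted p = 0.666 with an estimated correlation). Their mean log2 CPM was below the forage mean in 5 of 5 grain libraries for muscle, let-7 and miR-29 and in 3 of 5 for mesenchymal. It was below every forage library in 3 of 5 for muscle, 1 of 5 for let-7, 5 of 5 for miR-29 and 3 of 5 for mesenchymal. The exact permutation p of that mean before adjustment was 0.167 for muscle, 0.278 for mesenchymal, 0.103 for let-7 and 0.00794 for miR-29. The last is the smallest value that 252 arrangements allow. Adjusted over the list alone, miR-143 and miR-145 were called in muscle, and 0 members in the other 3 lists, where 3 mesenchymal, 1 let-7 and 1 miR-29 member had an unadjusted p under 0.05. Without FD_CON 2, whose miR-143 level was 286183 CPM, the adjusted p by camera was 0.212 for muscle, 0.0963 for mesenchymal, 0.115 for let-7 and 0.0963 for miR-29. The muscle call also ended without HG_CON 4 (0.176) or HG_CON 5 (0.0870). The mesenchymal call ended without any other forage control, HG_CON 1, HG_CON 2, HG_CON 4, HG_PHY 2 or HG_PHY 3 (up to 0.207), and the let-7 call without FD_CON 1, FD_CON 3, FD_CON 4, HG_CON 1, HG_CON 2, HG_CON 3 or HG_CON 5 (up to 0.150). Without miR-143 the muscle list had an adjusted p of 0.162 and without miR-199b the mesenchymal list 0.168, and with no filter the muscle, mesenchymal and let-7 lists did not pass (0.180, 0.0843 and 0.0843). With the 5 most abundant miRNAs left out the muscle list had 0.149 and the mesenchymal list 0.0516, with upper-quartile scaling the mesenchymal list had 0.0569, and with the largest member left out of all 4 lists at once the let-7 list had 0.0623.

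In PHY cows, miR-320a was at 2467 ± 385 CPM on forage and 3526 ± 282 CPM on grain (SD, n = 4 each; log2 change 0.51 ± 0.13) and hsa-miR-93-5p at 3372 ± 185 and 4325 ± 446 CPM (0.36 ± 0.12), both higher in 4 of 4 libraries. miR-146a (2026 ± 433 and 1203 ± 199 CPM; -0.75 ± 0.20), miR-181a (1139 ± 233 and 738 ± 118 CPM; -0.63 ± 0.19) and miR-181c (40.8 ± 10 and 26.5 ± 3.52 CPM; -0.62 ± 0.20) were lower in 4 of 4. Leukocyte miRNAs were lower in 8 of 10 members with a median of -0.31. When adjusted over the list alone, 4 were called, miR-146a, miR-142-3p (-0.52 ± 0.20), miR-142-5p (-0.41 ± 0.16) and miR-342 (-0.40 ± 0.14).

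edgeR called 0 of 468 miRNAs in PHY cows, with 30 at an unadjusted p under 0.05. DESeq2 called 0, limma-voom with quality weights 1 (miR-320a) and limma-trend, run on the authors' values, called 0. The adjusted p was 0.230 for miR-320a and miR-146a, 0.358 for miR-181a and 0.426 for miR-181c and hsa-miR-93-5p. The leukocyte list was the only list called by camera (adjusted p = 0.0217; adjusted p = 0.601 with an estimated correlation), lower in 4 of 4 grain libraries. Its call ended without FD_PHY 2 (adjusted p = 0.0852), HG_PHY 1 (0.0559) or HG_PHY 4 (0.0600), and without miR-146a (0.0698). The muscle list had 5 of 6 members below 0 (median -0.31) and the stratified epithelium list 7 of 7 above 0 (median 0.23), and neither passed camera in the model of 4 groups (adjusted p = 0.0659 each). Both passed with the replicate number as a block. The muscle score was below every forage library in 4 of 4 grain libraries (exact permutation p = 0.0286 before adjustment, the same as for leukocyte), and the epithelial score was above the forage mean in 4 of 4 (0.0571). The muscle list passed without FD_CON 2 (adjusted p = 0.0116) or FD_PHY 1 (0.0166), and the epithelial list without FD_PHY 1 (0.0166) or HG_PHY 3 (0.0492). Adjusted over the list alone, edgeR called miR-184 in the epithelial list, miR-146a and miR-181a in the inflammation list, and 0 muscle members, with 1 at an unadjusted p under 0.05. Whether the diet effects of the arms differ is tested by the interaction.

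**Figure D2:**
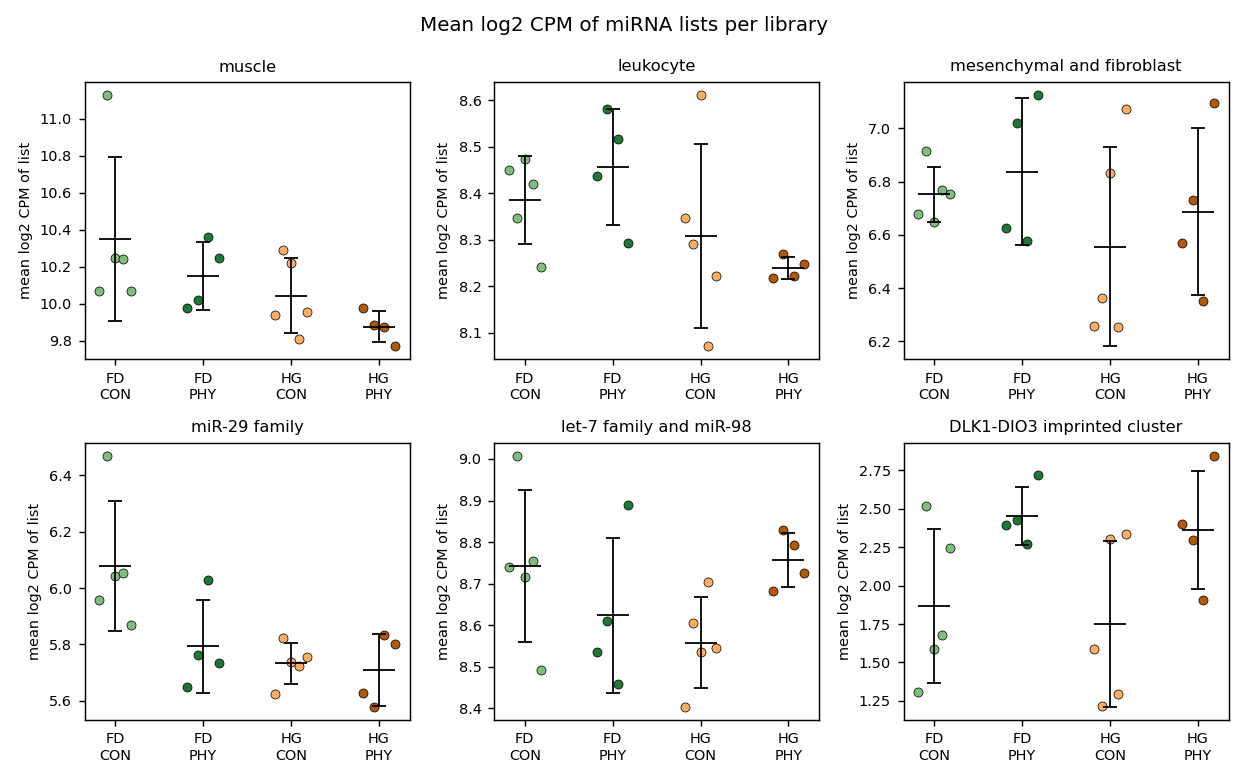
Mean log2 CPM over the measured members of 6 miRNA lists (y axis, not starting at 0) in each library, by group (x axis), with the mean and SD of each group as a line and bars. The miR-29 family averaged 6.08 in FD_CON and 5.73 in HG_CON, and the DLK1-DIO3 cluster 1.87 in FD_CON, 2.45 in FD_PHY, 1.75 in HG_CON and 2.36 in HG_PHY.

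The comparison of PHY with control cows on forage involved different cows, and the labels do not state whether the supplement was being fed. miR-190a (chromosome 10) was at 33.04 ± 16.4 CPM in FD_CON (SD, n = 5) and 7.998 ± 1.73 CPM in FD_PHY (SD, n = 4), a log2 difference of -2.05 ± 0.48, lower in 4 of 4 PHY libraries. miR-365-3p (2057 ± 780 and 1371 ± 98.8 CPM; -0.59 ± 0.21) and miR-677 (25.01 ± 9.82 and 15.3 ± 1.71 CPM; -0.71 ± 0.28) were also lower in 4 of 4 (log2 differences of -0.34 without FD_CON 2 and -0.44 without FD_CON 3), and hsa-miR-409-3p (11.8 ± 5.24 and 22.0 ± 6.86 CPM; 0.90 ± 0.35) and miR-379 (111 ± 39.1 and 176 ± 23.8 CPM; 0.66 ± 0.28), both on chromosome 21, were higher in 4 of 4. Below every FD_CON library were 2 of 4 PHY libraries for miR-365-3p and 3 of 4 for miR-677. Of the DLK1-DIO3 imprinted cluster, to which miR-379 belongs, 37 of 39 members were higher in PHY (median 0.52), and of the miR-29 family 9 of 9 were lower (median -0.27, and -0.13 without FD_CON 2 or -0.12 without FD_PHY 1).

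edgeR called 0 of 468 miRNAs, with 20 at an unadjusted p under 0.05, limma-voom and limma-trend called 0 and DESeq2 called 1, miR-190a. The adjusted p in edgeR was 0.156 for miR-190a and 0.926 for the other 4. The DLK1-DIO3 list passed camera at 3.27e-12 (adjusted p = 0.498 with an estimated correlation), with a mean log2 CPM above that of FD_CON in 4 of 4 libraries, and the miR-29 list at 0.0123 (adjusted p = 0.498 with an estimated correlation), below it in 4 of 4. The arms overlapped, as 1 of 4 PHY libraries was above every FD_CON library for DLK1-DIO3 and 3 of 4 were below every one for miR-29. The exact permutation p before adjustment was 0.0873 for DLK1-DIO3 and 0.0556 for miR-29. Adjusted over the list alone, edgeR called 0 members of either, with 4 DLK1-DIO3 members and 1 miR-29 member at an unadjusted p under 0.05. The miR-29 call ended without FD_CON 2 (0.155), FD_PHY 1 (0.0573) or FD_PHY 4 (0.0517) and with the filter of 10 CPM in 4 libraries (0.0859), and miR-190a passed without FD_CON 4 (adjusted p = 0.0115) or HG_CON 4 (0.0497). The muscle list (6 of 6 lower) and the let-7 list (15 of 17 lower) did not pass camera (adjusted p = 0.156 each), but muscle passed without FD_PHY 3 (0.0434) and let-7 without FD_PHY 4 (0.0144).

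On grain, miR-190a was at 26.96 ± 15.1 CPM in HG_CON (SD, n = 5) and 8.44 ± 3.29 CPM in HG_PHY (SD, n = 4), a log2 difference of -1.68 ± 0.47, lower in 4 of 4. miR-181a (1109 ± 229 and 738 ± 118 CPM; -0.59 ± 0.18) and miR-181c (39.98 ± 5.96 and 26.5 ± 3.52 CPM; -0.59 ± 0.19) were lower in 4 of 4. miR-193a-5p (187 ± 32.1 and 269 ± 11.1 CPM; 0.53 ± 0.13) and let-7e (615 ± 182 and 1055 ± 219 CPM; 0.78 ± 0.20) were higher in 4 of 4. The DLK1-DIO3 cluster was higher in 36 of 39 members (median 0.50, with 0.84 without HG_CON 5 and 0.30 without HG_PHY 4), with miR-379 at 112 ± 45.7 and 169 ± 56.6 CPM.

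edgeR called 0 of 468 miRNAs on grain, with 31 at an unadjusted p under 0.05. limma-voom and limma-trend called 0 and DESeq2 called 2, miR-190a and miR-193a-5p. The adjusted p in edgeR was 0.232 for miR-193a-5p and let-7e, 0.290 for miR-190a, 0.318 for miR-181a and 0.319 for miR-181c. Without HG_CON 4 edgeR called 3, miR-193a-5p and let-7e (adjusted p = 0.0152 each) and miR-190a (0.0470). The DLK1-DIO3 list passed camera at 1.06e-06 (adjusted p = 0.808 with an estimated correlation), above the control mean in 4 of 4 libraries, with an exact permutation p of 0.0952 before adjustment. The list's mean was above every HG_CON library in 2 of 4. Adjusted over the list alone, 0 of its members were called by edgeR, with 4 at an unadjusted p under 0.05, and let-7e and miR-181a were called in the let-7 and the inflammation list.

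**Figure D3:**
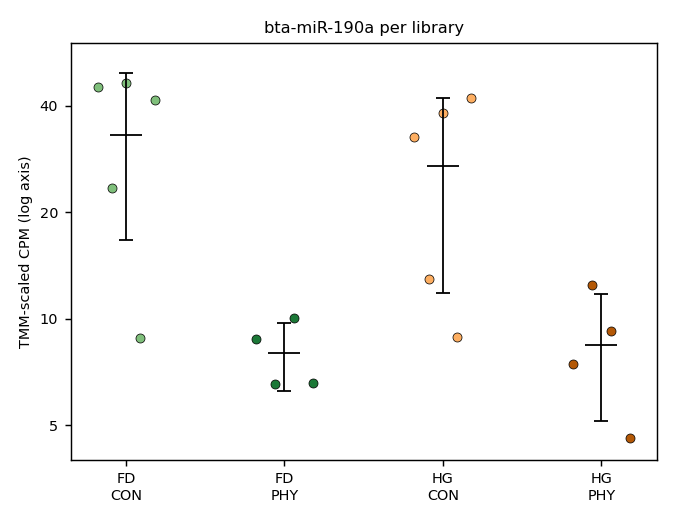
TMM-scaled CPM (counts scaled to a common library size, y axis, logarithmic) of miR-190a in each library, by group (x axis), with the mean and SD of each group as a line and bars. FD_CON 4 (8.86 CPM) and HG_CON 4 (8.88 CPM) lay at the level of the PHY libraries, whose highest value was 12.5 CPM.

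The interaction asked whether the diet effect differed between PHY and control cows. miR-193a-5p was at 234 ± 19.8 CPM in FD_CON, 187 ± 32.1 in HG_CON, 221 ± 26.9 in FD_PHY and 269 ± 11.1 in HG_PHY (SD, n = 5, 5, 4 and 4), an interaction of 0.61 ± 0.19 on the log2 scale. miR-22-5p (0.58 ± 0.20) and miR-222 (0.54 ± 0.23) had a diet effect above 0 in PHY and below 0 in control cows, and for miR-142-5p (-0.50 ± 0.21) it was the other way round. For miR-181c the interaction was -0.60 ± 0.26, with diet effects of -0.62 in PHY and -0.02 in control cows. In the let-7 family the interaction was above 0 in 16 of 17 members with a median of 0.35, for instance let-7e at 0.63 ± 0.29, let-7c at 0.43 ± 0.32, let-7g at 0.35 ± 0.16 and miR-98 at 0.32 ± 0.19.

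edgeR called 0 of 468 miRNAs for the interaction, with 11 at an unadjusted p under 0.05, and DESeq2, limma-voom and limma-trend called 0. The adjusted p was 0.885 for miR-193a-5p and 0.997 for miR-22-5p, miR-142-5p, miR-222 and miR-181c. Camera called the let-7 list (adjusted p = 0.00297; adjusted p = 0.446 with an estimated correlation). Its mean log2 CPM was below the forage mean in 5 of 5 control libraries on grain and above it in 4 of 4 PHY libraries. The diets overlapped, as 1 of 5 HG_CON libraries was below every FD_CON library and 0 of 4 HG_PHY libraries above every FD_PHY library. Adjusted over the list alone, edgeR called 0 let-7 members, with 2 at an unadjusted p under 0.05. The stratified epithelium list had 7 of 7 members above 0 (median 0.32) and did not pass camera in the model of 4 groups with all libraries (adjusted p = 0.0586). It passed with the replicate number as a block, and without FD_CON 2 (0.00840), FD_PHY 1 (0.0103), HG_CON 4 (0.0303), HG_CON 5 (0.0281) or HG_PHY 3 (0.0284). Across the 275 miRNAs with at least 10 CPM, which are not independent replicates, the diet effects in CON and in PHY had a Pearson r of 0.341 (Spearman's rho 0.340), and 5 of 100 relabellings of the PHY libraries gave an r as large. These were random draws from 70 arrangements, so they could repeat or return the real labelling.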

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

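Chosen after the results were seen were the tests of muscle against other cell types, of mesenchymal miRNAs outside the DLK1-DIO3 cluster, of the strongest list in the splits and the number of lists in those for the interaction, and of same-numbered libraries in miR-190a.

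Single libraries stood far from the rest of their group in 22 of 344 groups of libraries checked by Dixon's ratio over 86 miRNAs. Chance gives about 1 in 20 groups, here 17.2, and 8 of the 22 were in FD_CON 2. In that library miR-143 was at 286183 CPM (the other FD_CON libraries 133204 to 159075), miR-145 at 10602 (3850 to 5378), miR-133a at 50.17 (19.82 to 24.4) and miR-126-5p at 3664 (2203 to 2403). Also in FD_CON 2, miR-30b-5p was at 4178 CPM (others 1931 to 2314), miR-2484 at 74.53 (22.34 to 28.96), miR-365-3p at 3391 (1357 to 1931) and miR-369-5p at 6.292 (0.3411 to 2.013). FD_CON 2 also had the lowest quality weight of the 18 libraries in limma-voom, 0.478.

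In FD_PHY 4, miR-320a was at 3041 CPM (others 2233 to 2343), let-7e at 1089 (707 to 715.4), let-7g at 24182 (18595 to 19098) and miR-141 at 2513 (4045 to 4090). In FD_PHY 2, miR-378 was at 14283 CPM (11528 to 11836), and in FD_PHY 3 miR-21-5p was at 212182 (241063 to 246156). In HG_PHY 1, hsa-miR-93-5p was at 3662 CPM (4476 to 4631) and miR-181a at 563.1 (781.6 to 822.7). In HG_PHY 4, miR-142-5p was at 1709 CPM (1908 to 1926) and miR-30e-5p at 13621 (17215 to 17480). miR-30a-5p was at 44597 CPM in HG_CON 2 (20051 to 21511) and at 29889 in HG_PHY 3 (15720 to 17259). miR-193a-5p was at 243.5 CPM in HG_CON 4 (168.1 to 179.5), and miR-7 at 1347 in FD_CON 5 (675.4 to 825.6).

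For the interaction, camera called the let-7 list, with a median of 0.346 on the log2 scale over 17 members, of which edgeR called 0 over all miRNAs or over the list alone (2 at an unadjusted p under 0.05; DESeq2, limma-voom and limma-trend called 0 miRNAs). Chance could not be excluded. In 30 of 100 splits of the libraries the strongest of the lists had camera evidence as strong (-log10 scale 3.782, highest other 11.42). For the let-7 list alone only the real split of the 100 was as strong (highest other 3.459), but that count was run on a list chosen because it passed. As many lists past camera came from 63 of 100 splits (real 1, highest other 6). The list did not pass with an estimated correlation (adjusted p = 0.446) or with fry (0.335). It passed camera whichever single library was left out (adjusted p up to 0.02011) and under 8 of 8 other scalings, filters and counts (up to 0.01994), and no biological explanation was tested.

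The muscle, mesenchymal, leukocyte and miR-29 lists were lower on grain. Camera's calls at the preset correlation did not rest on FD_CON 2 alone, on a few abundant miRNAs, or on depth. Of the 4 lists, 4 passed without that library, 4 without the 5 most abundant miRNAs, and 4 with all libraries thinned to the lowest depth. But none of the 4 passed with an estimated correlation (0.668 for muscle, 0.3953 for mesenchymal, 0.1235 for leukocyte and 0.1987 for miR-29). Leaving the largest member out of all 4 lists at once ended all 4 calls, and other single libraries ended the leukocyte and mesenchymal calls. Passing camera again is therefore weak evidence against these causes. A lower share of every cell type other than the epithelium would lower the other markers alike. The muscle score differed from the mean of the erythroid, endothelial, columnar and neural scores (exact permutation p = 0.03345), and that mean was 0.09236 higher on grain. But muscle was picked because it fell, and those were lists that camera had not called. The leukocyte and mesenchymal lists, which fell, were left out. In the endothelial list miR-126-5p (-0.28), miR-126-3p (-0.18) and miR-218 (-0.22) were lower, and 3 of 6 members were above 0. The test therefore cannot decide on such a lower share. Chance could not be excluded, since 10 of 100 splits by diet within arm, the real split counted, gave as many lists (real 4, highest other 7). These splits moved libraries freely within an arm and did not swap the diets within a cow, so they do not test the paired design. A lower share of every other cell type and a change in the muscle or leukocyte share alone stay open. So do a change within cells and time, which runs with diet.

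The DLK1-DIO3 cluster was higher in PHY than in CON on both diets, and no single library accounted for it, as the lowest median over the libraries left out was 0.304. The list passed camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.498 on forage and 0.808 on grain). More mesenchymal cells in the PHY libraries would raise the 7 mesenchymal miRNAs outside the cluster by about as much. On forage 7 were lower in PHY (median -0.1577, range -0.5208 to -0.05466), where more such cells would raise them. The 7 were read in the same libraries and include more than 1 form of miR-199 and of miR-214, so they are not independent. On grain 4 were lower (median -0.03346, range -0.2925 to 0.2141). The gap to the cluster median was at least 0.3584 with any library left out. The SD of up to 0.1679 that it was set against is a spread over miRNAs and not over cows. Over libraries, the difference between the scores had an exact permutation p of 0.04762 on forage and 0.07143 on grain, before adjustment. On forage that p is close to 0.05 and comes from a test chosen after the results, so it cannot decide. More mesenchymal cells therefore stay open on both diets. Chance could not be excluded, since camera evidence as strong came from 6 of 100 splits on forage (-log10 scale 12.74, highest other 21.73) and 23 of 100 on grain (7.231, highest other 24.5), and in 6 and 24 of 100 the strongest of the lists was as strong. A difference between the cows of the arms and an effect of the supplement stay open.

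miR-190a was lower in PHY than in CON on both diets. The tables argue against reads shared with paralogs and a difference in depth as the whole cause, since the smaller of the log2 differences was -1.714 in adjusted counts and -1.714 after thinning, and in all 18 libraries the adjusted counts summed over the names of miR-190a equalled its raw count. Same-numbered libraries of an arm lay closer in miR-190a than other pairings (exact permutation p = 0.01944 over 2880 pairings, adjusted p = 0.2674 over 275 miRNAs), which is consistent with a stable difference between cows if the number marks the cow, and the labels do not say so. Within the controls alone the exact permutation p was 0.03333, and within the PHY cows 0.3333. A difference between the cows of the arms and an effect of the supplement stay open.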

How the results depend on the processing

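Chosen after the data were seen were the adjusted counts, the recovered reads, the exact permutation of list means, the largest member left out of 1 list at a time, and the lists without each library and under the other settings.

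Of 99 results for named miRNAs, 89 kept their direction under every alternative and 10 did not in at least 1. Leaving out single libraries gave 1735 values with the same direction and side of the threshold, 21 reversed, 11 newly past it and 14 no longer past it, and the other alternatives gave 1413, 7, 26 and 5. No scaling moved the median log2 change of all miRNAs by more than 0.1.

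In the averaged diet effect, 1 miRNA was called by edgeR. The count was 0 with upper-quartile scaling, 0 with the 5 most abundant miRNAs left out, 0 with 10 CPM in 4 libraries, 0 with names summed and 0 with limma-trend on the authors' table, with 55, 52, 44, 50 and 54 at an unadjusted p under 0.05. In these miR-320a had an adjusted p of 0.0552, 0.0597, 0.0529, 0.0619 and 0.0683, and its log2 change lay between 0.382 and 0.4751 over the libraries left out. The count was 3 with no filter, 12 with DESeq2 (5 up, 7 down), 3 with limma-voom and quality weights, 5 with the replicate number as a block (miR-320a, miR-143 and miR-146a at an adjusted p of 0.01107 each, miR-30c at 0.0255 and miR-30b-5p at 0.04884), 3 with that block in limma-voom (miR-320a, miR-143 and miR-146a, the last 2 at 0.01596), 3 at a threshold of 0.1, and 0 to 3 without single libraries. In PHY it was 1 with limma-voom and quality weights (miR-320a) and 1 with the replicate block (miR-146a). On forage it was 1 with DESeq2 and 0 to 1 without single libraries, and on grain 2 with DESeq2 and 0 to 3 without single libraries. In CON and for the interaction, every alternative gave 0, with 39 to 68 and 7 to 41 at an unadjusted p under 0.05 over the settings with all libraries of the groups compared. With 1 library left out, that number ran from 41 to 69 in the averaged diet effect, 27 to 62 in CON and 16 to 43 in PHY. It ran from 13 to 39 on forage, 23 to 50 on grain and 6 to 24 for the interaction. The cause was not tested.

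Camera called 4 lists in the averaged diet effect. The count was 0 with an estimated correlation, 0 with fry, 0 with fry and the replicate block, 0 by exact permutation, 0 with the largest member left out of all called lists at once, 2 with it left out of 1 list at a time, and 2 to 5 without single libraries. In CON 4 lists were called, with 0, 0, 0 and 0 by the first 4 of these tests, 1 and 2 without the largest members, 2 with the 5 most abundant miRNAs left out, 1 with no filter, and 0 to 4 without single libraries. In PHY 1 was called, with 0, 0, 0 and 0 by those tests, 3 by camera with the replicate block, 0 and 0 without the largest members, and 0 to 3 without single libraries. In PHY the block added stratified epithelium (adjusted p = 0.0388 by camera) and muscle (0.0498). On forage 2 were called, with 0 by an estimated correlation, fry and exact permutation, 1 with 10 CPM in 4 libraries, and 1 to 3 without single libraries. On grain 1 was called, with 0 by those 3 tests and 1 whichever single library was left out. Within an arm or a diet, the permutation had too few arrangements for a single list to pass after adjustment. For the interaction 1 was called, with 0 by an estimated correlation, fry, and fry with the replicate block, 2 by camera with the replicate block, and 1 to 2 without single libraries. There the block added stratified epithelium (adjusted p = 0.0259 by camera). The cause was not tested.

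Reversed in the averaged diet effect with limma-voom and quality weights were miR-200c (0.02736), miR-144 (-0.03374), miR-375 (-0.02249), miR-26a (0.01901) and let-7f (0.01629), and with names summed let-7f (0.002525) and miR-205 (0.0001916). Without single libraries, the log2 change ran from -0.007029 to 0.1416 for miR-200b, -0.03228 to 0.1028 for miR-24-3p, -0.04831 to 0.2772 for miR-144, -0.02064 to 0.2573 for miR-375 and -0.0848 to 0.03172 for miR-26a. It ran from -0.1191 to 0.05719 for let-7a-5p, -0.06389 to 0.06989 for let-7f, -0.04875 to 0.02144 for miR-205 and -0.07471 to 0.1919 for miR-30a-5p. The cause was not tested. The replicate numbers were not taken to pair the libraries, because the labels do not say that a number marks a cow and only 3 of the 9 same-numbered pairs had a correlation of deviations above 0.1 (range -0.01644 to 0.393). Their mean was 0.1096, against -0.03079 for other numbers within arm, and 6 of 18 libraries correlated best with their own number, a hint from the data and not from the design.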

Other observations

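The count over all miRNAs of closer same-numbered libraries was a test chosen after the result for miR-190a was seen.

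DESeq2 called 12 miRNAs in the averaged diet effect, 5 higher and 7 lower on grain. Higher were miR-320a, miR-25, hsa-miR-93-5p, the hypoxia-induced miR-210 and miR-484, and lower were miR-143, miR-145, miR-146a, miR-30b-5p, miR-30c, miR-125a and miR-125b. miR-484 and miR-125a fell outside the rule for named miRNAs and were chosen after their values were seen. In edgeR they had log2 changes of 0.27 ± 0.09 and -0.40 ± 0.12, and neither passed.

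The differences between the PHY and control arms were compared between the diets. Over 275 miRNAs, which are not independent replicates, the differences on forage and on grain had a Pearson r of 0.432 and a Spearman's rho of 0.194. Both came from the same cows, so stable differences between cows give a positive r with no effect of the supplement. Of 100 relabellings of the grain libraries 2 gave an r as large (median 0.02628), but relabelling parts the libraries of a cow, so these values do not stand for stable differences between cows alone. The relabellings were random draws that could repeat or return the real labelling.

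Chance could not be excluded for the numbers of miRNAs at an unadjusted p under 0.05. As many came from 7 of 100 splits for the averaged diet effect (real 49, highest other 73), 18 of 100 in CON (47, 78), 6 of 35 in PHY (30, 55), 40 of 100 on forage (20, 67), 28 of 100 on grain (31, 64) and 81 of 100 for the interaction (11, 62). The 1 miRNA called in the averaged diet effect was matched in 7 of 100 splits (highest other 3). Each count of splits given here and above includes the real split. The splits by diet did not keep the libraries of a cow together, so they do not test the paired design.

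Same-numbered libraries lay closer than other pairings within arm in 46 of 275 miRNAs at an exact permutation p under 0.05, against 13.75 by chance. A share of 0.001389 of the 2880 pairings gave as many (highest other 49), so chance pairing of the numbers is unlikely to account for the count. That the number marks the cow is a hypothesis from these data only, which the labels do not state.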
